A study of Mus musculus with 6 samples.

How the data were processed

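Bulk RNA of the mouse line RAW264.7 was measured in 6 libraries, 3 treated with vehicle and 3 with 25-HC for 24 h. Per the labels' protocols, libraries were made with the TruSeq RNA kit of Illumina from 1 µg of total RNA. Per the submitters' processing notes, HISAT2, StringTie, RSEM and the mouse genome build GRCm39 were used, with no versions and no order given. The annotation release and the strand setting are not given in the sources used here. The authors deposited 1 table of TPM per gene and library, with 2 decimals and a total of 1000000 TPM per library (1000001 in 25-HC 2 from rounding), and 11 empty columns that were ignored. TPM divides by transcript length and by library total, so it keeps no depth and no counts, and no interval from counting could be given. A gene that takes a large share of a library lowers all others there.

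A total of 2623 genes had no symbol and were named by their identifier. Where a symbol stood for several identifiers, the one with the highest mean TPM kept the symbol. Groups and replicate numbers came from the sample titles, and no pair of libraries held identical values. Genes with a mean of at least 1 TPM over the 6 libraries (12092) were tested on log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a mean-variance trend, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 differences are on that scale, which understates changes of genes with low TPM, while folds are ratios of mean TPM. All 6 libraries entered the fit and no block was used. Values listed at 0 can be failed estimates, so no fold is given against them.

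Gene lists for cholesterol synthesis, sterol sensing and uptake, LXR targets, fatty acid synthesis, ATF4 targets, endoplasmic reticulum chaperones, NRF2 targets, pro-inflammatory and alternative activation genes, interferon-stimulated genes, S phase, mitosis, p53 targets, lysosome, glycolysis, oxidative phosphorylation, macrophage identity, other cell types, ribosomal proteins, mitochondrial mRNAs, immediate early genes and heat shock chaperones were fixed before the data were examined, as were the test, most other settings tried and the rule for naming genes. Lists with at least 5 measured genes were tested with limma camera (preset correlation 0.01), adjusted over the lists, with camera with an estimated correlation and fry beside it. Camera sets a list against the other genes, while fry tests whether its genes move one way. Called lists were those under 0.05 with the preset correlation. The named genes are the 8 largest increases and decreases among called genes with at least 5 TPM and no overlap between groups, 15 genes of sterol and macrophage biology, and per list the called members (up to 4) or else the gene with the smallest p. Only Snord16a met the first part, and other genes are said to be chosen after their values were seen. Some genes that the rule names are not reported here. Non-overlap was counted as every 25-HC library above, or below, every vehicle library.

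The settings chosen at that point, each tried in place of the main one, were a pseudocount of 0.1 or 5, no filter or a mean of at least 5 TPM, median-ratio rescaling, quantile normalization, removal of mitochondrial genes, robust moderation, no variance trend, a replicate block, and leaving out each library. Chosen after seeing the data were a correction for transcript length (a loess trend per library, span 0.75, degree 2, subtracted), the length slope of each library as a covariate, protein-coding genes only, and vehicle 3 alone against 25-HC. Lengths and GC content were those of the longest transcript in GENCODE release M21, matched by gene identifier for 11132 (92.1%) of the tested genes. That release uses another genome build, so no coordinates were taken from it. List medians were also set against 10000 random lists of equal size drawn within 10 bins of expression and 6 of length, for 13 lists chosen after seeing the data. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used. Simulations used only the 6503 genes with a mean of at least 10 TPM, so recovery among lower genes was not examined. With independent noise of the size seen among the 25-HC libraries, limma recovered 97% of genes changed by 1 on the log2 scale. Of genes changed by 2 it recovered 100%. With the real deviations of the 6 libraries from their group means it recovered 0% and 11%, and 10.5% and 50.5% after the length correction (6187 genes).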

Results

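RNA from the mouse macrophage-like cell line RAW264.7 was sequenced after 24 h with vehicle or with a compound that the labels abbreviate as 25-HC, with 3 libraries per group. The labels used here give neither the full name of the compound nor its dose. The series title places the experiment in a study of how miR-9-5p secreted by cancer cells affects cholesterol homeostasis, and the comparison asks which transcripts differ between treated and vehicle macrophages. The deposited table holds TPM values (transcript abundance scaled for length and library total) for each gene, scaled to the same total in each library, so sequencing depth is unknown. Nothing in the labels says that the libraries came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. The 3 libraries treated with 25-HC were close to each other, with 11990, 11971 and 12005 genes at 1 TPM or more and a Pearson r across genes of 0.972 to 0.976. The vehicle libraries were not: vehicle 1, 2 and 3 had 11238, 9492 and 11994 such genes, and r among them was 0.807 to 0.938. Vehicle 3 was nearer to the treated libraries (r of 0.963 to 0.965) than vehicle 1 (0.924 to 0.931) or vehicle 2 (0.792 to 0.802). Genes are not independent replicates in these correlations. In vehicle 1 and 2, longer transcripts were lower: relative to the mean of the 25-HC libraries, the median log2 difference went from 0.18 for the shortest sixth of the genes to -0.78 for the longest in vehicle 1, from -0.051 to -1.63 in vehicle 2, and from 0.051 to 0.039 in vehicle 3. Ribosomal protein genes took 26.9%, 37.4% and 21.01% of the TPM in vehicle 1, 2 and 3, against 22.9% to 23.2% in the 25-HC libraries.

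**Figure D1:**
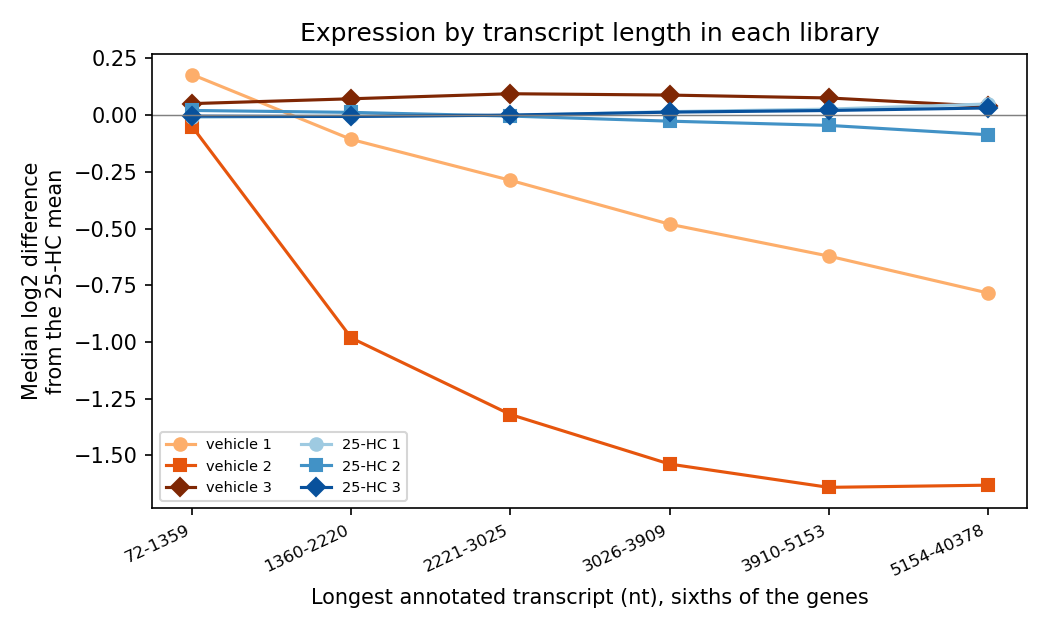
Median log2(TPM + 1) difference of each library from the mean of the 25-HC libraries (a 25-HC library is set against the other 25-HC libraries), for sixths of the tested genes by length of the longest annotated transcript in nucleotides; each line is 1 library. Vehicle 1 and vehicle 2 fall to -0.78 and -1.63 in the longest sixth, while vehicle 3 stays at 0.039.

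On the deposited values, macrophages given 25-HC had more transcript from the cholesterol synthesis pathway, from ATF4 target genes and from interferon-stimulated genes than every vehicle library. None of these 3 lists passed limma camera with an estimated correlation on those values (adjusted p = 0.99, 0.99 and 0.985). All 20 cholesterol synthesis genes and all 15 measured interferon-stimulated genes (of 28 listed) were higher in each 25-HC library than in each vehicle library, as were 23 of 27 ATF4 targets. Of all 12092 genes tested, 2736 (22.6%) showed this separation upward and 979 (8.1%) downward. Chance gives 5% each way only if all 6 libraries are alike in spread. Here the vehicle libraries were scattered and the 25-HC libraries close together, so chance alone can give more than 5%. Shifts of a whole library also move many genes at once. After median-ratio rescaling the numbers of separated genes were 2225 (18.4%) and 2187 (18.1%), so the excess upward rests on the scaling. There 16 of the 20 cholesterol synthesis genes, 10 of the 15 interferon-stimulated genes and 18 of the 27 ATF4 targets separated. That rescaling divides each library by 1 factor, 0.423 in vehicle 2 and 0.967 to 1.32 in the others. It does not follow the trend with transcript length. The gene-level test passed only Snord16a, a small nucleolar RNA hosted in an intron of a ribosomal protein gene, so that reads of its host can reach it. It was listed at 0 TPM in the 3 vehicle libraries and at 24.4, 29.0 and 36.7 TPM in the 25-HC libraries (adjusted p = 0.0168 by limma, higher in 3 of 3 treated libraries), a call lost in 8 of 18 other settings. Its log2 difference is set by the pseudocount, at 4.94 with 1, 8.21 with 0.1 and 2.79 with 5. No gene was lower at that threshold, and 1352 genes (996 higher, 356 lower) had an unadjusted p under 0.05. That balance also moved with the scaling, to 1095 higher and 890 lower after median-ratio rescaling, 1169 and 1168 after quantile normalization, and 1031 and 1005 after the correction for transcript length. Without vehicle 3 the limma test called 671 genes higher and 51 lower, without vehicle 2 it called 9 and 4, and without any single 25-HC library it called none (431 to 488 genes at an unadjusted p under 0.05).

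The median log2 difference of all tested genes was 0.52. This shift was not subtracted from the differences, list medians, folds or separations given here. Camera and the matched random lists do set a list against other genes. The median over all genes was -0.010 after median-ratio rescaling, which called 1 gene higher and 1 lower, and 0.020 after quantile normalization, which called 4 and 1. The exact permutation test of 1 gene with 3 libraries against 3 cannot give a p below 0.1.

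The cholesterol synthesis enzymes had a median log2 difference of 1.78 between 25-HC and vehicle. The list of 20 genes was higher than other genes (limma camera adjusted p = 6.36e-09), with adjusted p = 0.99 with an estimated correlation. None of its genes passed over all genes tested, and 18 did when adjusted over the list alone. Hmgcs1, an early enzyme of the pathway, was at 5.25 ± 5.29 TPM in vehicle (SD, n = 3) and at 17.9 ± 0.765 TPM in 25-HC (SD, n = 3). Sqle, which oxidises squalene, was at 13.1, 3.42 and 24.9 TPM in vehicle 1, 2 and 3 and at 45.7, 42.6 and 44.3 TPM in the 25-HC libraries. Fdps, which makes farnesyl diphosphate, was even among vehicle libraries (213 ± 13.8 TPM) and stood at 493 ± 10.4 TPM in 25-HC, a 2.31-fold difference. This was 1.33-fold with overlapping libraries after median-ratio rescaling. Its log2 difference was 1.21 as deposited, 1.14 after quantile normalization and 0.63 after length correction. Against vehicle 3 alone the median of the list was 0.81. That library lacked the trend with transcript length, but it shared a trend with transcript GC content with vehicle 1 and 2 (given below). After median-ratio rescaling of all libraries the median of the list was 1.27, with 16 of 20 genes separated. With an estimated correlation the list had adjusted p = 0.0479 after that rescaling, 0.0507 after length correction, 0.0779 after quantile normalization and 0.428 without vehicle 2. Fry, which does not set a list against other genes, gave adjusted p = 0.167 as deposited and 4.69e-04, 0.00106, 0.00102 and 0.0384 in these settings.

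Genes of sterol sensing and cholesterol uptake were higher in all 13 measured cases by their means, 9 of them without overlap, or 7 after median-ratio rescaling (median log2 difference 1.48, limma camera adjusted p = 3.76e-04, adjusted p = 0.99 with an estimated correlation). Adjusted over the list alone, 3 passed. The median was 0.96 without vehicle 2, 0.92 after median-ratio rescaling, 0.68 after length correction and 0.46 against vehicle 3 alone. Insig1, the SREBP-retaining protein and itself an SREBP target, was at 3.80, 1.64 and 8.32 TPM in vehicle 1, 2 and 3 and at 35.0, 31.3 and 32.5 TPM in 25-HC (log2 difference 2.79, SE 0.48, adjusted p = 0.389 by limma). Srebf2, the transcription factor of the pathway, was at 28.7 ± 21.9 TPM in vehicle and 72.9 ± 3.44 TPM in 25-HC (SD, n = 3 each). The values of Insig2 overlapped, with 5.93, 0.94 and 16.2 TPM in vehicle and 18.9, 15.0 and 19.2 TPM in 25-HC. Ch25h, which makes 25-hydroxycholesterol, was listed at 0 in all 6 libraries.

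**Figure D2:**
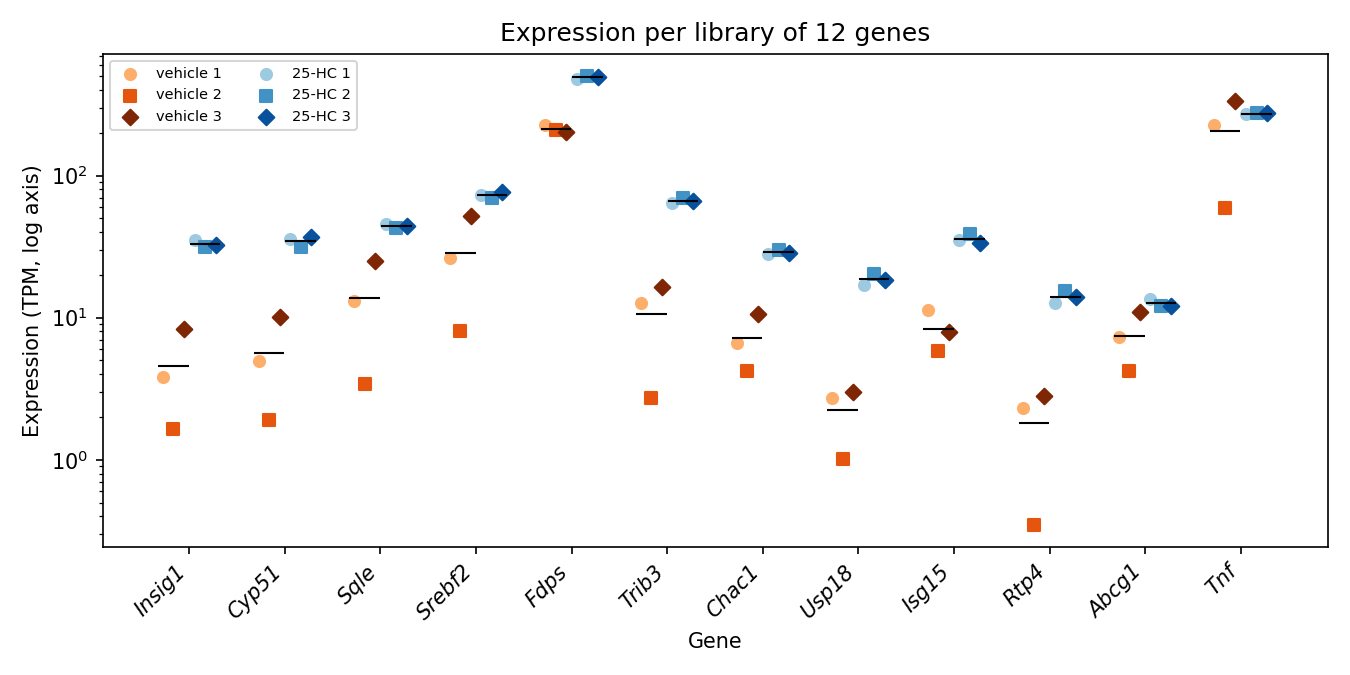
Expression in TPM (log axis) of 12 genes in each of the 6 libraries; points are libraries and horizontal bars are group means of 3. The genes were picked for display, and Cyp51, Trib3, Isg15 and Rtp4 were chosen after their values were seen. For 11 of the genes the 25-HC libraries lie above each vehicle library, as for Insig1 (31.3 to 35.0 against 1.64 to 8.32 TPM). Of all genes tested 22.6% do so. Fdps and Abcg1 overlap after median-ratio rescaling. For Tnf the 25-HC libraries lie between vehicle 1 and vehicle 3.

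Targets of the oxysterol receptor LXR were not called as a list (11 measured, median log2 difference 0.68, or 0.42 without vehicle 2, limma camera adjusted p = 0.66). None passed over all genes and 1 did when adjusted over the list alone, and 5 of the 11 separated upward and 1 downward (3 and 2 after median-ratio rescaling). Abcg1, a cholesterol exporter and LXR target, was at 7.49 ± 3.41 TPM in vehicle and 12.6 ± 0.765 TPM in 25-HC (SD, n = 3 each); its values overlapped after median-ratio rescaling. Abca1, another exporter, was barely detected, at 0.01, 0.01 and 0.04 TPM in vehicle and 0.14, 0.13 and 0.13 TPM in 25-HC. Srebf1, which encodes the SREBP of fatty acid synthesis, was at 13.1 ± 11.9 TPM in vehicle and 31.2 ± 2.06 TPM in 25-HC. Scd1, the stearoyl-CoA desaturase, was at 1.29, 0.34 and 3.59 TPM in vehicle and at 14.5, 11.5 and 10.4 TPM in 25-HC. Lpl and Apoe, chosen after their values were seen, overlapped between groups, with Lpl at 58.6 TPM in vehicle 3 and 54.6 ± 3.82 TPM in 25-HC and Apoe at 6.61 ± 1.46 TPM in vehicle and 5.17 ± 1.12 TPM in 25-HC.

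Genes of fatty acid and triglyceride synthesis were higher than other genes (20 measured, median log2 difference 1.08, limma camera adjusted p = 9.38e-04, adjusted p = 0.99 with an estimated correlation). None passed over all genes, 1 did when adjusted over the list alone, and 14 separated upward (12 after median-ratio rescaling, with 1 downward). Fads2, a fatty acid desaturase, was at 14.6, 11.9 and 25.8 TPM in vehicle and at 53.4, 53.6 and 54.1 TPM in 25-HC. Fasn, the fatty acid synthase, chosen after its values were seen, overlapped: it was at 94.7 ± 45.7 TPM in vehicle and 109 ± 2.65 TPM in 25-HC (SD, n = 3 each), and lower in 25-HC than in vehicle 3, at 132 TPM. After median-ratio rescaling Fasn was lower in each 25-HC library than in each vehicle library (0.82-fold). The median of the list was 0.57 after median-ratio rescaling, 0.64 without vehicle 2 and 0.26 against vehicle 3 alone.

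The ATF4 targets of the integrated stress response, which cover amino acid synthesis, transport and stress signalling, had a median log2 difference of 1.36 over 27 measured genes (limma camera adjusted p = 2.70e-07, adjusted p = 0.99 with an estimated correlation). All 27 had a higher mean in 25-HC, and 12 passed when adjusted over the list alone. Chac1, a glutathione-degrading enzyme induced through ATF4, was at 7.14 ± 3.23 TPM in vehicle and 28.9 ± 0.773 TPM in 25-HC (SD, n = 3 each), 2.73-fold above vehicle 3. Trib3, Cth and Asns were chosen after their values were seen. Trib3, a pseudokinase, was at 12.6, 2.71 and 16.6 TPM in vehicle and at 64.2, 69.4 and 66.7 TPM in 25-HC. Cth, which makes cysteine from cystathionine, was at 7.92, 0.75 and 12.2 TPM in vehicle and at 48.2, 46.1 and 46.9 TPM in 25-HC. Asns, the asparagine synthetase, was at 163 ± 41.8 TPM in vehicle and 341 ± 1.03 TPM in 25-HC; its values overlapped after rescaling. The median of the list was 0.53 against vehicle 3 alone and 0.82 after median-ratio rescaling, where 18 genes separated, and 0.81 without vehicle 2. With an estimated correlation the list had adjusted p = 0.0435 after that rescaling, 0.0565 after length correction, 0.221 after quantile normalization and 0.649 without vehicle 2. The fry test gave adjusted p = 0.253 as deposited and 2.84e-04, 0.00229, 0.00761 and 0.0472 in these settings.

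Endoplasmic reticulum chaperones were less clearly apart, with a median log2 difference of 1.10 over 19 genes (limma camera adjusted p = 0.032, adjusted p = 0.99 with an estimated correlation) that was 0.37 without vehicle 2 and 0.071 against vehicle 3 alone. None of them passed over all genes or adjusted over the list alone, and 13 separated upward (11 after median-ratio rescaling, with 2 downward). Herpud1, which acts in the degradation of misfolded proteins, was at 41.7, 12.8 and 61.0 TPM in vehicle and at 137, 138 and 137 TPM in 25-HC. The lysosome list, of hydrolases and membrane proteins, had a median log2 difference of 1.11 over 22 genes (limma camera adjusted p = 3.76e-04, adjusted p = 0.99 with an estimated correlation). Its median was 0.55 without vehicle 2, 0.49 after median-ratio rescaling and 0.31 against vehicle 3 alone. Of the 22 genes, 19 separated upward (14 after rescaling) and none passed either adjustment, over all genes or adjusted over the list alone. Gla, the lysosomal alpha-galactosidase, was at 17.4 ± 7.58 TPM in vehicle and 49.6 ± 3.84 TPM in 25-HC (SD, n = 3 each).

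Interferon-stimulated genes had a median log2 difference of 1.65 over 15 measured genes of 28 listed (limma camera adjusted p = 6.36e-09, adjusted p = 0.985 with an estimated correlation, fry adjusted p = 0.0342). None passed over all genes, and 14 passed adjusted over the list alone. Only these 15 passed the filter on the mean of all 6 libraries, which low genes pass more easily when they are higher in 25-HC. Without that filter the median of the list was 0.86. Usp18, which deconjugates ISG15 and restrains interferon receptor signalling, was at 2.70, 1.02 and 2.98 TPM in vehicle and at 17.1, 20.4 and 18.4 TPM in 25-HC, 6.25-fold above vehicle 3. Isg15, Rtp4 and Irf7 were chosen after their values were seen. Isg15, a ubiquitin-like modifier, was at 8.36 ± 2.80 TPM in vehicle and 35.8 ± 2.62 TPM in 25-HC. Rtp4 was at 1.82 ± 1.30 TPM in vehicle and 14.1 ± 1.45 TPM in 25-HC. Irf7, an interferon-inducing transcription factor, was at 9.47, 11.7 and 8.53 TPM in vehicle and at 28.8, 25.8 and 25.9 TPM in 25-HC; its 2.71-fold difference was 1.45-fold with overlap after rescaling. Against vehicle 3 alone the median was 1.17; after median-ratio rescaling it was 1.18 with 10 genes separated. With an estimated correlation the list had adjusted p = 0.0435 after that rescaling, 0.0507 after length correction, 0.0981 after quantile normalization and 0.101 without vehicle 2. In these settings fry gave adjusted p = 9.49e-04, 0.00106, 0.0029 and 0.00103.

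**Figure D3:**
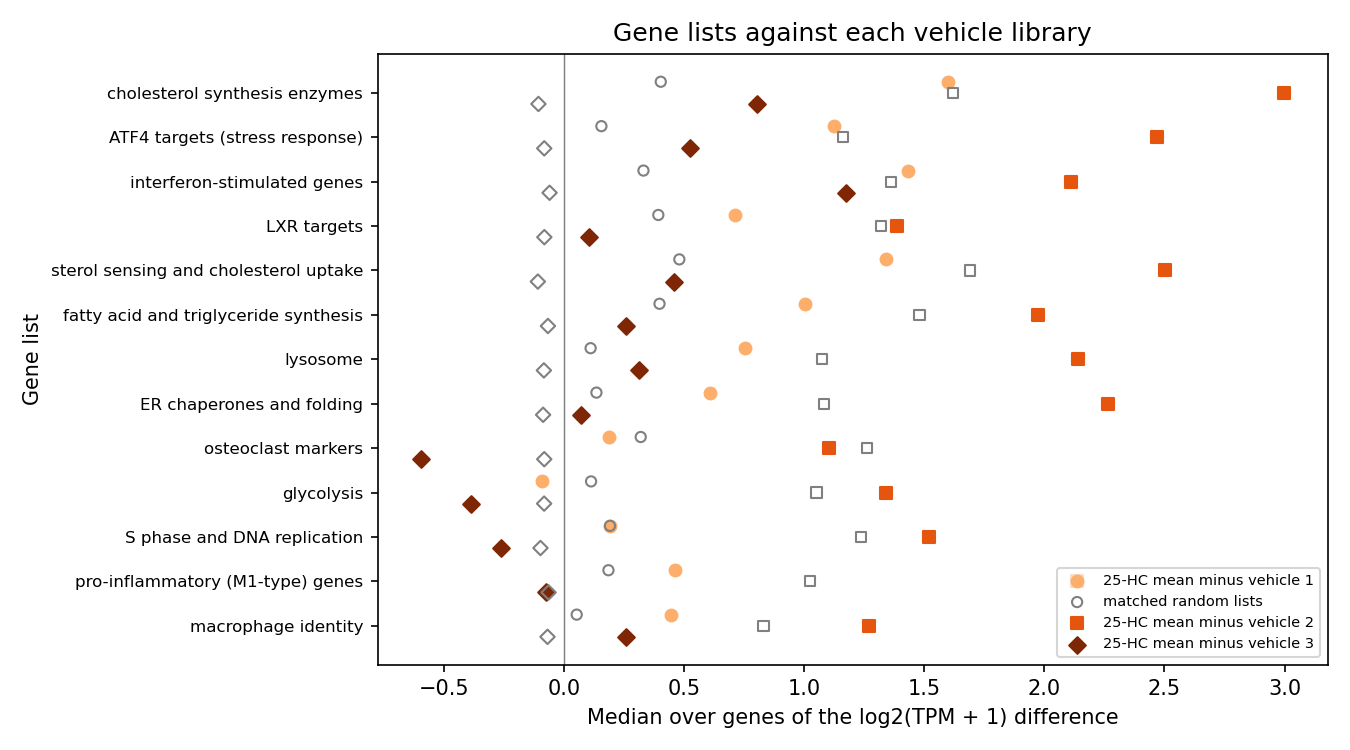
Median over the genes of each list of the log2(TPM + 1) difference between the 25-HC mean and each vehicle library; filled points are the lists, open grey points of the same shape are the medians of 10000 random lists matched on expression and transcript length. For cholesterol synthesis enzymes the medians are 1.60, 2.999 and 0.81 against vehicle 1, 2 and 3, where matched lists give 0.40, 1.62 and -0.11.

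Inflammatory and identity genes of the macrophage were not called as lists on the deposited values. Pro-inflammatory genes (23 measured) had a median log2 difference of 0.82 (limma camera adjusted p = 0.504) and alternative activation genes (10 measured) one of 0.71 (adjusted p = 0.738), and these medians were 0.24 and 0.23 without vehicle 2. Tnf was at 226, 59.2 and 334 TPM in vehicle and at 271, 274 and 274 TPM in 25-HC. Il1b was at 5.02, 1.40 and 5.82 TPM in vehicle and at 2.51, 2.65 and 2.14 TPM in 25-HC, and Nos2 was at 4.02 ± 4.06 TPM in vehicle and 4.79 ± 0.481 TPM in 25-HC (SD, n = 3 each). After median-ratio rescaling Il1b was lower in each 25-HC library than in each vehicle library (0.449-fold). Tlr4, the lipopolysaccharide receptor, was at 1.09, 0.29 and 3.05 TPM in vehicle and at 5.53, 5.36 and 5.20 TPM in 25-HC. Arg1, a marker of alternative activation, was at most 0.13 TPM. Trem2, a lipid-sensing receptor of the same list, was at 216 ± 17.9 TPM in vehicle and 372 ± 4.26 TPM in 25-HC, with overlap after rescaling. The macrophage identity list had a median of 0.67 over 16 genes (0.22 without vehicle 2, limma camera adjusted p = 0.66). It was called higher in 2 of 21 other settings. Of its genes 8 separated upward and 2 downward (5 and 3 after median-ratio rescaling). Fcgr1, the high-affinity Fc gamma receptor, was at 17.9 ± 3.60 TPM in vehicle and 34.9 ± 1.95 TPM in 25-HC, with overlap after rescaling. Cx3cr1 of the same list was lower in each 25-HC library than in each vehicle library (values below). Osteoclast markers (9 genes, median 0.37, adjusted p = 0.738; Atp6v0d2 at 2.34 ± 1.11 and 3.81 ± 0.0681 TPM) and dendritic cell markers (5 genes, median -0.21, adjusted p = 0.393; Cd83 at 23.1 ± 7.89 and 34.6 ± 1.56 TPM, with overlap after rescaling) did not pass either. The osteoclast median turned to -0.20 without vehicle 2 and to -0.59 against vehicle 3 alone, and that list was called lower in 2 of 21 other settings. Markers of neutrophils, lymphocytes, fibroblasts and epithelial cells had too few measured genes to test (1, 1, 0 and 0) and summed to at most 4.96, 4.73, 1.68 and 0.58 TPM in any library. Prtn3 (1.58 ± 0.390 TPM in vehicle, 2.01 ± 0.892 TPM in 25-HC) and Cd79b (3.34 ± 0.772 and 2.78 ± 0.534 TPM) were the measured neutrophil and lymphocyte genes. Of these lists, 1 alternative activation gene and none of the others passed adjusted over the list alone.

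Proliferation, metabolism and oxidative stress lists did not pass limma camera on the deposited values. The median log2 difference was 0.61 for S phase genes (23 measured, adjusted p = 0.968), 0.75 for mitotic genes (22, adjusted p = 0.0771), 0.62 for p53 targets (17, adjusted p = 0.66) and 0.42 for NRF2 targets (17, adjusted p = 0.738). It was 0.29 for glycolysis (16, adjusted p = 0.187) and 0.11 for nuclear-encoded oxidative phosphorylation (24, adjusted p = 0.191). Without vehicle 2 these medians were -0.018 for S phase, 0.11 for mitotic genes, 0.13 for p53 targets, -0.031 for NRF2 targets, -0.25 for glycolysis and -0.011 for oxidative phosphorylation. After median-ratio rescaling they were 0.035, 0.40, 0.16, -0.20, -0.34 and -0.52 in the same order. Glycolysis was called lower in 6 of 21 other settings, among them median-ratio rescaling (median -0.34, adjusted p = 0.0449), length correction (-0.19, adjusted p = 0.0389) and without vehicle 2 (adjusted p = 1.91e-04), with adjusted p from 5.78e-08 to 0.99 over all settings. In these 3 settings glycolysis had adjusted p = 0.244, 0.219 and 0.649 with an estimated correlation. Mitotic genes were called higher in 3 settings, S phase genes lower in 2 and oxidative phosphorylation lower in 1. After quantile normalization the mitotic call (adjusted p = 0.0264) was lost with an estimated correlation (adjusted p = 0.724), which was not tried in the other settings of these calls. The medians of the S phase, glycolysis, oxidative phosphorylation and osteoclast lists are above 0 while their tests point down, since the test sets them against the other genes. No gene of these lists passed over all genes or adjusted over the list alone. Gadd45a, a p53-responsive growth arrest gene, was at 2.91, 0.37 and 3.76 TPM in vehicle and at 13.0, 12.0 and 12.0 TPM in 25-HC. Eno1, the glycolytic enolase, was at 833 ± 249 TPM in vehicle and 512 ± 12.8 TPM in 25-HC (SD, n = 3 each). Sqstm1, an autophagy receptor and NRF2 target, was at 362 ± 187 TPM in vehicle and 718 ± 2.17 TPM in 25-HC. Mki67 was at 0.937 ± 0.511 and 3.19 ± 0.248 TPM, Rfc4 at 44.9 ± 4.61 and 33.2 ± 0.399 TPM, and Ndufa4, which overlapped after rescaling, at 1028 ± 193 and 772 ± 18.0 TPM in vehicle and 25-HC.

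Among lists that track RNA quality and handling, ribosomal protein genes were lower than other genes (18 measured, median log2 difference -0.083, limma camera adjusted p = 0.00669, adjusted p = 0.99 with an estimated correlation). Rps24 was at 5903, 10796 and 3950 TPM in vehicle 1, 2 and 3 and at 3666, 3869 and 3664 TPM in 25-HC, with overlap after rescaling. The direction of this list turned to 0.036 after quantile normalization and to 0.086 against vehicle 3 alone. Mitochondrially encoded mRNAs (13 genes, median 0.16, adjusted p = 0.968, with a mean of 0.032 and a test that points down), immediate early genes (13 genes, median 0.65, adjusted p = 0.968) and heat shock chaperones (10 genes, median 0.69, adjusted p = 0.66) did not pass. Without vehicle 2 the medians of these 3 lists were 0.69, -0.21 and -0.0089, and that of the ribosomal protein list was -0.017. After median-ratio rescaling the 3 medians were -0.47, 0.17 and 0.091, and that of the ribosomal protein list was -0.71. Adjusted over the list alone, 2 mitochondrial genes, 1 immediate early gene and none of the ribosomal protein or heat shock genes passed. mt-Co2 was at 78.9, 42.3 and 97.6 TPM in vehicle and at 251, 234 and 628 TPM in 25-HC, values that reads shared with nuclear copies can shift. Klf2, a transcription factor, was at 3.79 ± 1.71 TPM in vehicle and 19.5 ± 0.859 TPM in 25-HC, and Hsp90aa1, a cytosolic chaperone, at 9.64 ± 3.65 and 23.4 ± 0.593 TPM (SD, n = 3 each).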

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

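The length correction, the length-slope covariate, protein-coding genes only and vehicle 3 alone were chosen after seeing the data; the other settings were chosen beforehand. The counts of called genes moved most with the choice of vehicle libraries, and the only call of the main test was also lost without any single 25-HC library. The main test gave 1 gene higher, 0 lower and 1 at least 2-fold changed, and 7 lists higher and 1 lower. Genes higher, lower and changed at least 2-fold by limma numbered 0, 0 and 0 with a pseudocount of 5, without a filter and at a mean of at least 5 TPM (1687, 2189 and 722 genes at an unadjusted p under 0.05), 1, 1 and 2 after median-ratio rescaling, 4, 1 and 5 after quantile normalization, 17, 3 and 20 after length correction, 1, 2 and 3 with the length-slope covariate, 0, 0 and 0 with protein-coding genes only (1212 unadjusted), and 547, 765 and 173 for vehicle 3 alone, a single library assumed to vary like the 25-HC libraries. Leaving out 1 library at a time gave 0 to 671 genes higher, 0 to 51 lower and 0 to 717 changed at least 2-fold, the highest without vehicle 3. With 2-decimal TPM and no counts, depth limits cannot be computed.

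Lists called lower numbered 0 without a filter and after quantile normalization, 2 after median-ratio rescaling, 3 with the length-slope covariate and with protein-coding genes only, and 5 for vehicle 3 alone. Camera with an estimated correlation called 0 lists higher and 0 lower, and fry 1 and 0. The cholesterol synthesis, sterol uptake, fatty acid, ATF4 and lysosome lists kept their call in 19 of 21 settings and the interferon list in 20; the chaperone list kept it in 16 and the ribosomal protein list in 13. The ribosomal protein median reversed to 0.036 after quantile normalization, 0.030 with the length-slope covariate and 0.086 for vehicle 3 alone. The test of mitochondrial mRNAs reversed to higher, with medians of 0.69 without vehicle 2 (-0.27 to 0.69 on leaving out 1 library, adjusted p = 4.06e-04, or 0.316 with an estimated correlation), 0.81 with the length-slope covariate and 0.60 for vehicle 3 alone. Against vehicle 3 alone, NRF2 targets reversed to -0.29, immediate early genes to -0.48, Tnf to -0.29 and Fasn to -0.28. The cause was not tested. Of the comparisons of single genes with their main value, 1148 kept their direction and their side of the threshold, 26 changed direction with no call in either, 2 reversed, 104 moved past the threshold and 8 fell below it. Those 8 were all Snord16a, whose call was lost with a pseudocount of 5, without a filter, at a mean of at least 5 TPM, with the replicate block, and without vehicle 1 or any 25-HC library (adjusted p between 0.00488 and 0.415 over 18 settings).

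With the replicate block the test called 0 genes higher, 0 lower and 0 changed at least 2-fold, against 1, 0 and 1 without it, and 1163 genes had an unadjusted p under 0.05. Deviations of libraries that share a number correlated at -0.013, 0.056 and 0.030 across genes, which shows no pairing by number. It cannot exclude one, since the spread among the vehicle libraries was far larger than among the 25-HC libraries and could hide it.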

Other observations

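Chosen after the results were seen were the tests on length-corrected values, of transcript length and GC content, and of rescaled outlying genes. So were those of markers of other cell types, against matched random lists and over splits. The genes first named here were chosen after their values were seen. After the correction for transcript length, limma called 17 genes higher and 3 lower with 25-HC, and these include genes outside the lists. Most other settings did not reproduce these calls. Of the 20 genes, 0 passed as deposited, after median-ratio rescaling, with the length-slope covariate or without any single 25-HC library. After quantile normalization 3 passed, without vehicle 2 it was 4, and without vehicle 3, where 671 genes were called higher, it was 17. H2-T24, a class I histocompatibility gene, was at 4.13 ± 2.53 TPM in vehicle and 23.8 ± 0.610 TPM in 25-HC (SD, n = 3 each). Lgals9, a beta-galactoside-binding lectin, was at 4.69, 2.81 and 5.56 TPM in vehicle and at 22.4, 25.6 and 23.1 TPM in 25-HC. Tsc22d3, a glucocorticoid-induced leucine zipper gene, was at 1.98 ± 1.17 and 10.2 ± 0.190 TPM, and Irak3, an inhibitor of Toll-like receptor signalling, at 3.55 ± 2.64 and 15.1 ± 0.141 TPM. Aldh1l2, a mitochondrial folate enzyme, was at 0.94, 0.44 and 3.63 TPM in vehicle and at 14.1, 11.3 and 12.7 TPM in 25-HC. Arl11, Rhox5 and Gm42687 were also higher, Gm42687 being listed at 0 in the vehicle libraries and at 5.78, 6.99 and 14.3 TPM in 25-HC. The remaining higher calls were Insig1, Cyp51, Msmo1, Scd1, Chac1, Klf2, Usp18, Isg15 and Rtp4. For Insig1 the length-corrected log2 difference was 2.25 (SE 0.18, adjusted p = 0.0262 by limma, 0.0149 to 0.62 over its other settings).

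The 3 genes called lower after that correction were Cd72, a lectin-like inhibitory receptor, Serinc2, a membrane protein, and Dmpk, a kinase. Cd72 was at 188, 84.9 and 241 TPM in vehicle and at 76.5, 88.4 and 90.4 TPM in 25-HC, where the deposited values overlap, with a length-corrected log2 difference of -1.40 (SE 0.15, adjusted p = 0.0489 by limma, 0.025 to 0.62 over its other settings). Serinc2 was at 32.7, 12.6 and 39.0 TPM in vehicle and at 8.60, 10.1 and 10.5 TPM in 25-HC. Dmpk was at 33.8, 13.0 and 46.1 TPM in vehicle and at 14.7, 14.01 and 15.1 TPM in 25-HC. Akr1b8, Cx3cr1 and Fcgr2b, chosen after their values were seen, were not called (adjusted p = 0.389 each as deposited, and 0.119, 0.142 and 0.111 after length correction). Akr1b8, an aldo-keto reductase, was even among the vehicle libraries at 466 ± 19.5 TPM and stood at 210 ± 10.5 TPM in 25-HC. Cx3cr1, the fractalkine receptor and a gene of the macrophage identity list, was at 60.5, 48.0 and 79.1 TPM in vehicle. It was lower, at 41.8, 34.4 and 28.2 TPM, in 25-HC. Fcgr2b, an inhibitory Fc receptor, was higher, at 16.4 ± 10.96 TPM in vehicle and 76.8 ± 3.24 TPM in 25-HC.

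Vehicle 1 and vehicle 2 stand apart from the other 4 libraries. Their difference from the 25-HC mean correlated with transcript length across genes (Spearman -0.444 in vehicle 1 and -0.341 in vehicle 2, against -0.0302 in vehicle 3 and 0.144, -0.226 and 0.111 in the 25-HC libraries, where the medians by length stay between -0.086 and 0.049), which may reflect loss of long transcripts through RNA degradation or library preparation, kinds of loss that TPM cannot separate. A few abundant genes taking a larger share of the TPM do not account for it alone, since 6324 genes stayed over 2-fold from the 25-HC mean in vehicle 2 after median-ratio rescaling, against 417 in vehicle 3. RNA from fibroblasts, epithelial cells, lymphocytes or neutrophils is also argued against, as their markers summed to 10.7 TPM in vehicle 2 and to 6.79 to 8.93 TPM in the 25-HC libraries. No biological explanation was tested, as all 3 libraries carry the same label. All 3 vehicle libraries also shared a trend with the GC content of transcripts (share of G and C bases). Their difference from the 25-HC mean correlated with it at 0.205, 0.192 and 0.185 (Spearman) in vehicle 1, 2 and 3. In the 25-HC libraries, each against the other 25-HC libraries, this was -0.0007, 0.043 and -0.032. The trend divides the groups, and neither the length correction nor the matched random lists allow for it. Its cause was not tested.

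The sterol, ATF4 and interferon lists could be higher in 25-HC only because vehicle 1 and 2 lost signal from long transcripts. Against each vehicle library separately, each list lay above random lists matched on expression and length. The lowest percentile over the 3 vehicle libraries was 100 for cholesterol synthesis, 99.99 for ATF4 targets and 98.5 for interferon-stimulated genes. Against vehicle 3, which lacked that loss, the list medians were 0.81, 0.53 and 1.17, where matched lists gave -0.11, -0.082 and -0.060. A loss that follows length alone, as binned here, thus does not account for the whole difference. Other library effects are not excluded, as the random lists were not matched on GC content. Random lists lack the shared regulation of a pathway, and other lists passed the same bar. The lowest percentile was 99.8 for lysosome, 98.3 for sterol sensing and uptake and 98.5 for chaperones. The fatty acid and triglyceride synthesis list did not reach it, at 95.97 against vehicle 2. Against vehicle 3 most of the 13 lists lay near an end of the random lists, so a far percentile is common there. Macrophage identity was at 100, fatty acid synthesis at 99.99, S phase at 0.54 and glycolysis and osteoclast markers at 0. Against vehicle 2 macrophage identity, S phase, glycolysis and osteoclast markers were at 81.8, 81.2, 73.5 and 35.1. Pro-inflammatory genes were at 99.99 against vehicle 2 and at 45.6 against vehicle 3. If 25-HC is 25-hydroxycholesterol, an oxysterol known to hold back SREBP processing and to activate LXR, higher SREBP targets would be the opposite of its textbook effect. An exchange of labels between the groups cannot be told apart from a true rise. The LXR targets cannot decide it, as their percentiles, between 56.4 and 93.3, reach neither end of the random lists. Their list also includes Srebf1 and Scd1, whose means were higher in 25-HC like those of the SREBP targets. Srebf1 was not called in any setting. A response to 25-HC stays open as a hypothesis.

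The count of called genes was set against the other ways to split the 6 libraries into 3 and 3. With only 10 splits no share under 0.05 can be reached. For called genes the real split gave 1 and the highest other split 1, and 3 of the 10 gave as many. For called lists the real split gave 8 and the highest other 12, in the split that joins vehicle 2 with 25-HC 1 and 3, and 4 of the 10 gave as many. After length correction the real split gave 20 genes and the highest other 2, so 1 of the 10, the real one, gave as many; for lists after that correction the real split gave 8 and the highest other 11, and 5 of the 10 gave as many.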
